A study of Homo sapiens with 4 samples.

How the data were processed

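Total RNA was extracted from H9 human embryonic stem cells with Trizol and made into Illumina libraries, per the labels' protocols, which name no step of poly(A) selection or ribosomal RNA removal. One table of the whole series was used. Per the file headers, it gives for each of 15942 genes the gene symbol, its RefSeq transcripts, RPKM values (reads scaled by transcript length and library total) and read counts for 4 libraries. Read counts were deposited by the authors as whole numbers without normalization, and the RPKM values were deposited by the authors beside them. Reads were handled with STAR and DESeq2 on the genome build hg19, per the submitters' processing notes, which give no versions or roles. Whether counting used strand, and how multimapping or repeated reads were treated, is not given in the sources used here. Values of genes with overlapping or antisense partners, of paralogs and of ribosomal protein genes with processed pseudogenes are therefore uncertain.

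Libraries were grouped by their labels into 2 siLuc controls and 2 siUPF1 libraries. Both control count columns carry the same name, so they stand for the control group without a replicate number and are called control a and control b in the order of the table. For the same reason 2 columns of control RPKM values were not used. The siUPF1 RPKM values served only to derive the transcript length behind each gene, as counts divided by RPKM and library total. The median ratio of this length to the reference transcript length was 0.990 over 4870 genes with a single transcript. Dividing counts by this length gave reads per transcript base, with a median of 0.166, and of genes with at least 100 counts none exceeded 1.12.

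Depth ranged from 8887239 to 11200973 counts per library, siUPF1 replicates together being 12.9% deeper than the controls, and the 10 most abundant genes took 0.643% to 0.693% of the counts. At this depth counting error is small for genes at 100 CPM and large for genes near 1 CPM. Libraries of a group differed by more than sampling noise (chi-square divided by degrees of freedom 1.72 for the controls and 2.88 for siUPF1, against 8.81 to 9.59 across groups), so no library was treated as a copy of another. The biological coefficient of variation was 4.47%.

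The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3 on the counts, with TMM normalization, the filterByExpr filter, which kept 15557 genes and left out 385, and Benjamini-Hochberg adjustment at 0.05. With 2 libraries per group the test borrows its estimate of spread across genes. The SE of a log2 fold change was its size divided by the square root of F. CPM values are TMM-scaled. The test was tested on simulated data for the siUPF1 against control comparison, with counts drawn for 15557 genes and 200 of them changed. It recovered 89% of the genes changed 2-fold and 66% of those changed 1.41-fold, with 2 false calls. The counts were drawn with the spread that edgeR itself had estimated, alike in both groups and without any trend on reads per base. The result therefore holds under the assumptions of the test and does not measure false calls in the real libraries.

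Before the data were examined, 26 gene lists were fixed, of which 25 had at least 5 tested members. Each was tested with camera from limma 3.58.1 on log2 CPM (preset inter-gene correlation 0.01, two-sided, adjusted over the lists), with UPF1 left out of every list. Transcript features came from GENCODE release 29 on GRCh38, matched by current or older symbol for 13541 of 14064 coding genes (96.3%). Only features were taken from it, and no coordinates are given, because the table was made on hg19 and holds none. A long 3' UTR was one of at least 2668 nt, the upper quartile. Upstream AUGs were sought in the 5' UTR of the longest coding transcript, and a gene with no annotated 5' UTR counted as having none.

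The genes to name were set by a rule before the data were examined. They were UPF1, the 10 largest rises and 10 largest falls among genes past an adjusted p of 0.05 with a mean of at least 5 CPM and no overlap between the groups, and for each list the 3 members with the smallest p. The rule had set 1 RPKM as the floor for a table with RPKM values. Since control RPKM columns could not be tied to libraries, the 5 CPM floor written for counts was used. Genes named outside the rule are marked as such. Some genes that the rule names are not reported here.

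Alternatives chosen before the data were examined were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 5 CPM in 2 libraries, an adjusted p of 0.1, a fold of at least 2, each library left out, and for lists an estimated correlation and fry. Added after the data were seen were genes under 0.25 reads per base only, and a fit with the trend on reads per base removed from each library (loess, span 0.3). Leaving out a library leaves 1 in its group, which is then assumed to vary like the other group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.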

Results

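RNA from H9 cells, an established human embryonic stem cell line, was sequenced after transfection with a small interfering RNA (siRNA) against luciferase, which has no target in human cells, or with an siRNA against UPF1. UPF1 is the RNA helicase at the core of nonsense-mediated RNA decay (NMD), the pathway that degrades transcripts whose translation stops early or ahead of an exon junction. There were 2 control libraries and 2 siUPF1 libraries, and the deposited table held read counts for 15942 genes. The counts summed to 8887239 and 9937231 in the control libraries, called control a and control b here because the table gives both the same name, and to 10058515 and 11200973 in siUPF1 replicates 1 and 2. The treatment text shared by all libraries also names an actinomycin D time course and an siRNA against UPF3A, and it gives no time for a library. Nothing says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The study examined how gene expression in human embryonic stem cells differs upon loss of UPF1.

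The siRNA target was lower in the siUPF1 libraries. UPF1 transcripts averaged 212 ± 10.1 CPM (counts scaled to a common library total of 1e+06; SD, n = 2) in the controls and 69.5 ± 12.3 CPM (SD, n = 2) after UPF1 siRNA, so that 32.8% of the control level remained, 28.7% in replicate 1 and 36.9% in replicate 2. The raw UPF1 counts were 1936 in control a, 2053 in control b, 608 in siUPF1 replicate 1 and 878 in siUPF1 replicate 2. UPF1 fell by 1.60 on the log2 scale (SE 0.07, adjusted p = 1.06e-102, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and both siUPF1 libraries lay below both controls. With the trend on reads per base removed, the adjusted p from this test was 5.89e-05.

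Among 15557 genes tested, 2613 rose and 1422 fell after UPF1 knockdown at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), together 25.9% of the genes tested. Most changes were small. The median fold was 1.38 among the risers and 1.25 downward among the fallers, and 394 genes rose and 144 fell by at least 2-fold. Both siUPF1 libraries lay above both controls for 2593 of the risers and below both for 1409 of the fallers. Over all tested genes the groups did not overlap for 63.4%, where chance gives 33.3% for 2 libraries against 2. The count of calls depended on the test and on the controls. DESeq2 called 1274 up and 465 down, and with control a left out edgeR called 1444 and 552, with control b left out 1583 and 610.

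Among genes at a mean of 5 CPM or more, the 10 largest rises lay between 2.49 and 2.91 on the log2 scale. EDN1, which encodes the vasoconstrictor peptide endothelin-1, rose from 1.33 ± 0.043 to 10.1 ± 2.10 CPM (SD, n = 2 per group), a log2 fold change of 2.91 (SE 0.27). GREM1, a secreted antagonist of bone morphogenetic proteins (BMPs), rose from 12.8 ± 2.31 to 74.5 ± 20.3 CPM, a log2 fold change of 2.52 (SE 0.11), and COL12A1, a collagen chain, rose from 28.1 ± 3.80 to 159 ± 28.3 CPM, a log2 fold change of 2.49 (SE 0.08). LIMCH1 rose by 2.69 (SE 0.12) and the glycosyltransferase gene GCNT4 by 2.69 (SE 0.13) on the log2 scale. The noncoding gene LOC283299 (2.81), the sphingomyelin synthase gene SGMS2 (2.63), the membrane protease gene TMPRSS13 (2.56), the kinase gene ALPK2 (2.49) and the connexin gene GJB2 (2.49) made up the rest of the 10 largest rises. The highest adjusted p among these 10 was 2.75e-20, for ALPK2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). With the trend on reads per base removed, the highest from this test was 0.00172, for GJB2.

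Among genes at the same mean of 5 CPM or more, UPF1 itself was among the 10 largest falls, 6 of which were larger. SPN, which encodes the leukocyte surface protein sialophorin, fell from 12.9 ± 0.773 to 2.65 ± 0.217 CPM (SD, n = 2 per group), a log2 fold change of -2.28 (SE 0.22). The dipeptidase gene DPEP1 changed by -1.82 (SE 0.19), the neuronal sodium channel gene SCN1A by -1.73 (SE 0.21), LRRC55 by -1.73 (SE 0.16), the LIM-only factor gene LMO3 by -1.71 (SE 0.13) and the homeobox gene HMX2 by -1.61 (SE 0.17). LOC101926975 (-1.54), C10orf105 (-1.51) and the Ras exchange factor gene RASGRP4 (-1.43) completed the 10. The fall of SCN1A and HMX2 differed between the siUPF1 libraries. It was -1.31 and -1.20 without replicate 1, and -2.40 and -2.25 without replicate 2. The highest adjusted p among the 10 was 5.19e-09, for RASGRP4 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). With the trend on reads per base removed, the highest from this test was 0.00161, for HMX2, and DESeq2 gave HMX2 an adjusted p of 0.0127.

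**Figure D1:**
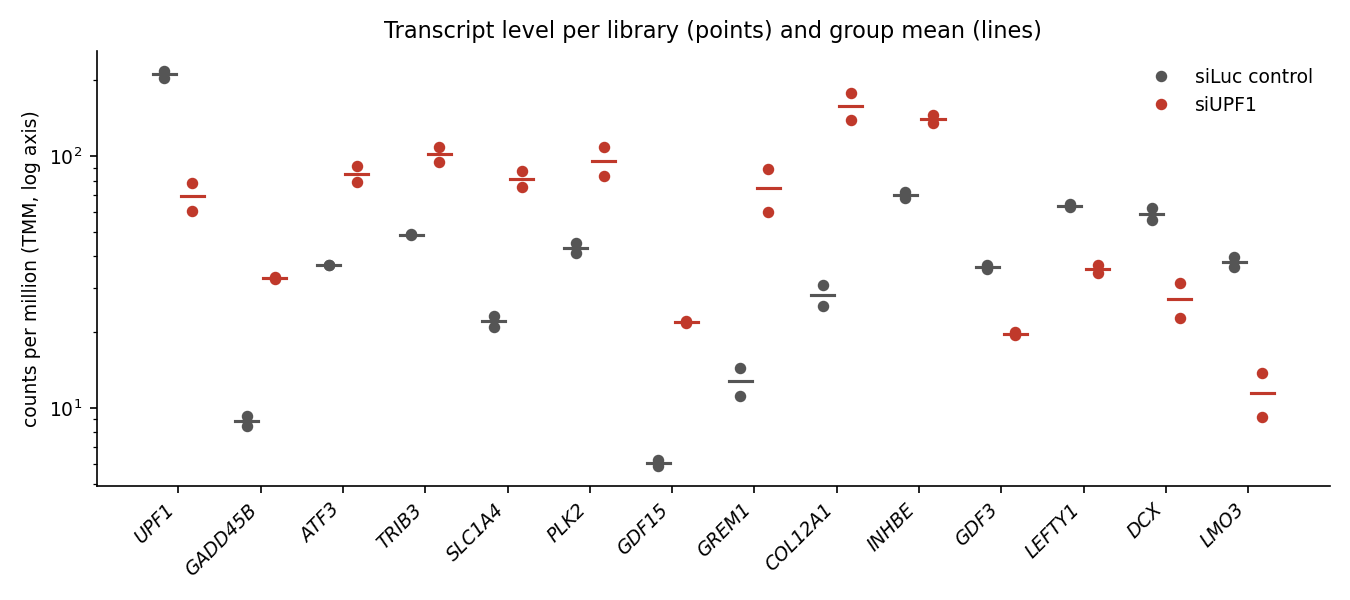
Transcript level of 14 genes in TMM-scaled CPM on a log axis; points are single libraries (grey, siLuc control; red, siUPF1; 2 per group) and lines are group means. UPF1 averaged 212 CPM in the controls and 69.5 CPM after knockdown, while GADD45B went from 8.88 to 32.9 CPM.

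Of 40 tested genes on a list of textbook NMD targets fixed before the data were examined, 24 rose, 2 fell and 14 did not pass (25 rose and 4 fell when adjusted over the list alone), with a median log2 fold change of 0.33. DESeq2 called 20 up and 0 down (23 and 2 at an unadjusted p under 0.05). GADD45B, a growth arrest and stress gene, rose from 8.88 ± 0.561 to 32.9 ± 0.371 CPM (SD, n = 2 per group), a log2 fold change of 1.88 (SE 0.14). The stress transcription factor gene ATF3 rose by 1.19 (SE 0.09) and the stress pseudokinase gene TRIB3 by 1.06 (SE 0.08). DDIT3 (1.28, SE 0.12) and GADD45A (0.86, SE 0.10), named after their values were seen, also rose. The list stood above other genes with the preset correlation (camera, Benjamini-Hochberg adjusted p = 4.77e-06), and the call was lost with adjusted p = 0.671 with an estimated correlation, within a range of 1.48e-09 to 0.671 over 10 alternatives. That correlation is estimated from 2 libraries per group, and under it 0 of 25 lists had an unadjusted p under 0.05. The adjustment gave the same 0.671 to all 8 lists called with the preset correlation. Their unadjusted camera p ran from 0.156 for p53 targets to 0.467 for splicing factors. Losing a call this way therefore does not set one list apart from another.

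Transcripts of the NMD machinery other than UPF1 moved little. Of 24 NMD factor genes, 6 rose and 18 did not pass (6 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.04. SMG9 rose by 0.55 (SE 0.08) and SMG1 by 0.36 (SE 0.07), both of which encode parts of the complex that phosphorylates UPF1, and UPF3B rose by 0.35 (SE 0.07). The adjusted p of UPF3B ranged from 2.46e-06 to 0.0533 over 11 alternatives, highest without control b (edgeR quasi-likelihood test). As a list they did not stand apart (camera, Benjamini-Hochberg adjusted p = 0.479). Host genes of small nucleolar RNAs, many of whose spliced transcripts are known NMD substrates, went both ways, with 7 up, 7 down and 13 not passing of 27 (8 and 8 adjusted over the list alone; camera, adjusted p = 0.798). The fallers numbered 3 without siUPF1 replicate 2, 1 without control b and 0 in edgeR without control a (3 at an unadjusted p under 0.05; DESeq2 called 1). NMD factor risers numbered 3 without control b, and without siUPF1 replicate 1 there were 3 NMD factor fallers and the list's median was 0.01. With the trend on read density removed, 11 NMD factors rose and the list had its lowest adjusted p, 0.0828, of a range that ended at 0.981 (camera). SNHG11 rose by 1.17 (SE 0.13), SNHG17 by 0.94 (SE 0.09) and SNHG15 by 0.63 (SE 0.10). Of the 27 host genes, 13 lay over 0.5 reads per base. Whether read density hid rises in either list was not tested.

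Of 37 tested genes of the integrated stress response, the programme driven by the transcription factor ATF4, 21 rose and 16 did not pass (22 rose adjusted over the list alone), with a median log2 fold change of 0.19. The amino acid transporter gene SLC1A4 rose from 22.1 ± 1.49 to 81.4 ± 8.60 CPM (SD, n = 2 per group), a log2 fold change of 1.87 (SE 0.09), and NUPR1, named after its value was seen, rose by 1.62 (SE 0.26). ATF4 itself, also named afterwards, did not pass at -0.11 (SE 0.07), with an adjusted p of 0.238 that ranged from 0.074 to 0.716 over 11 alternatives (edgeR quasi-likelihood test). ATF4 had 0.808 reads per transcript base, near where counts may level off, and whether this hid a rise was not tested. It stood at 0.0394 with the trend on read density removed. Of the 37 members, 20 lay over 0.5 reads per base. On the NMD target list are also 9 of the 37, ATF3, TRIB3 and DDIT3 among them. The list was called with the preset correlation (camera, Benjamini-Hochberg adjusted p = 5.74e-06) and lost with adjusted p = 0.671 with an estimated correlation (range 6.23e-12 to 0.671 over 10 alternatives). Chaperones of the endoplasmic reticulum and genes of the unfolded protein response went both ways, with 3 up, 6 down and 15 not passing of 24 (3 and 8 adjusted over the list alone; camera, adjusted p = 0.0715). The stress kinase gene EIF2AK3 rose by 0.32 (SE 0.08) and EDEM1 by 0.30 (SE 0.07), while SEC24D, a vesicle coat gene, changed by -0.25 (SE 0.07). Without control a, 0 of the 24 passed edgeR's test (2 up and 3 down at an unadjusted p under 0.05; DESeq2 on all libraries called 2 and 2), without control b or siUPF1 replicate 2 there were 2 fallers, and without siUPF1 replicate 1 there were 10 and the list was called (camera, adjusted p = 0.00895, the lowest of a range that ended at 0.801). Without control a EIF2AK3, EDEM1 and SEC24D had adjusted p of 0.121, 0.183 and 0.0871, the highest of their alternatives, whose lowest were 9.9e-05, 4.25e-05 and 0.00142 (edgeR quasi-likelihood test).

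Of 31 tested targets of p53, 18 rose, 1 fell and 12 did not pass, the same counts of risers and fallers adjusted over the list alone, with a median log2 fold change of 0.30. DESeq2 called 12 up and 0 down and limma-voom 17 and 0, with 1 down at an unadjusted p under 0.05 in each. GDF15, a secreted stress factor, rose from 6.05 ± 0.238 to 22.0 ± 0.200 CPM (SD, n = 2 per group), a log2 fold change of 1.86 (SE 0.17). The kinase gene PLK2 rose by 1.15 (SE 0.08), SESN2, which is also on the stress response list, by 0.69 (SE 0.07), and the cell cycle inhibitor gene CDKN1A, named after its value was seen, by 0.48 (SE 0.09). MDM2, which encodes the ligase that marks p53 for degradation, also named afterwards, stood at 0.08 (SE 0.07) and did not pass, with an adjusted p of 0.455 and a range of 0.237 to 0.845 over 12 alternatives (edgeR quasi-likelihood test). The list was called with the preset correlation (camera, Benjamini-Hochberg adjusted p = 2.56e-05) and lost with adjusted p = 0.671 with an estimated correlation (range 4.65e-06 to 0.671 over 10 alternatives).

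Of 31 pluripotency genes tested, 15 fell, mostly by small amounts, and 16 did not pass (20 fell adjusted over the list alone), with a median log2 fold change of -0.17. GDF3, a growth factor of undifferentiated cells, fell from 36.3 ± 0.75 to 19.7 ± 0.416 CPM (SD, n = 2 per group), a log2 fold change of -0.88 (SE 0.12), and DPPA2 changed by -0.60 (SE 0.14). UTF1 changed by -0.72 (SE 0.15), but by -0.37 without control a, where its adjusted p was 0.261, the highest of alternatives that began at 2.48e-06 (edgeR quasi-likelihood test). The core factor genes POU5F1 (-0.25, SE 0.07), SOX2 (-0.20, SE 0.07) and NANOG (-0.21, SE 0.07), named after their values were seen, passed the edgeR quasi-likelihood test with adjusted p of 0.00303, 0.0228 and 0.0229, and without control a these became 0.18, 0.493 and 0.415. Their lowest adjusted p over the alternatives were 0.000326, 0.0155 and 0.00921, and only SOX2 and NANOG reached their highest without control a. POU5F1 reached its highest, 0.199, with the trend on read density removed, where it stood at -0.08. Without control a the list held 2 fallers, and without siUPF1 replicate 2 it held 7; DESeq2 called 7. The list was called with the preset correlation (camera, Benjamini-Hochberg adjusted p = 2.56e-05) and lost with adjusted p = 0.671 with an estimated correlation (range 3.54e-06 to 0.671 over 10 alternatives). Its median log2 ratio was also -0.08 between the controls, b over a, and -0.07 between the siUPF1 libraries, 2 over 1.

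Markers of differentiated lineages went both ways. Among 9 endoderm genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), and the pioneer factor gene FOXA2 fell from 4.53 ± 0.628 to 0.567 ± 0.047 CPM (SD, n = 2 per group), a log2 fold change of -2.97 (SE 0.37), while the Nodal antagonist gene CER1 (1.13, SE 0.13) and AFP (0.88, SE 0.18) rose. Among 10 mesoderm genes, 5 rose and 3 fell (5 and 4 adjusted over the list alone), with BMP4 at 0.90 (SE 0.14), MSX2 at 0.82 (SE 0.17) and WNT3 at -0.55 (SE 0.11). Among 16 neural ectoderm genes, 8 rose and 5 fell, the same counts adjusted over the list alone, with SOX3 at 1.07 (SE 0.10), the neuronal microtubule gene DCX at -1.11 (SE 0.10) and the adhesion gene NCAM1 at -0.76 (SE 0.09). Among 10 trophoblast and amnion genes, 4 rose and 6 did not pass (5 rose adjusted over the list alone), with the transcription factor genes GATA3 at 1.19 (SE 0.26) and TFAP2C at 0.66 (SE 0.10), and IGFBP3 at 0.49 (SE 0.12). The adjusted p of IGFBP3 ranged from 7.19e-05 to 0.0539, highest without control a (edgeR quasi-likelihood test). None of these 4 lists was called (camera, Benjamini-Hochberg adjusted p = 0.996 for endoderm, 0.624 for mesoderm, 0.546 for neural ectoderm and 0.137 for trophoblast and amnion). Without control a, 4 neural genes rose, and without siUPF1 replicate 2, 4 rose and 3 fell. Mesoderm risers numbered 3 and trophoblast risers 2 without control a. The endoderm list had a median of -0.14 and a mean of -0.13, while camera placed it up, and the median was 0.23 without siUPF1 replicate 2 and 0.57 with a filter of 5 CPM.

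Members of developmental signalling pathways moved apart. Of 31 Activin, Nodal and TGF-beta pathway genes, 8 rose and 8 fell (8 and 10 adjusted over the list alone). INHBE, an activin subunit gene, rose from 70.3 ± 2.67 to 141 ± 7.72 CPM (SD, n = 2 per group). The Nodal feedback inhibitor gene LEFTY1 changed by -0.84 (SE 0.09), as did LEFTY2, named after its value was seen, by -0.70 (SE 0.09). Of 21 BMP pathway genes, 7 rose and 2 fell, the same counts adjusted over the list alone, with GREM1 and BMP4 as above and ID4 at 0.79 (SE 0.10). Of 22 WNT genes, 2 rose and 6 fell (2 and 9 adjusted over the list alone), with the receptor gene FZD5 at -0.34 (SE 0.07) and the feedback gene AXIN2 at -0.35 (SE 0.08). AXIN2 stood at -0.19 without siUPF1 replicate 1, with an adjusted p of 0.0687, the highest of alternatives that began at 2.18e-08 (edgeR quasi-likelihood test). Of 24 FGF and ERK genes, 5 rose and 8 fell, the same counts adjusted over the list alone, with FOSL1 at 1.58 (SE 0.12), the receptor gene FGFR3 at 1.06 (SE 0.09) and the phosphatase gene DUSP4 at 0.84 (SE 0.08). None of these lists was called (camera, Benjamini-Hochberg adjusted p = 0.397, 0.382, 0.145 and 0.18 in this order). With a filter of 5 CPM the WNT list was called (camera, adjusted p = 0.0117, the lowest of a range that ended at 0.801). The Activin list had a median of -0.06 and a mean of 0.09, and camera placed it down. Without control a, 5 rose and 4 fell of the Activin list, 4 fell of the FGF list and 3 fell of the WNT list, and neither WNT riser passed without control a or without siUPF1 replicate 2 (1 and 2 at an unadjusted p under 0.05 in edgeR; DESeq2 called 0).

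**Figure D2:**
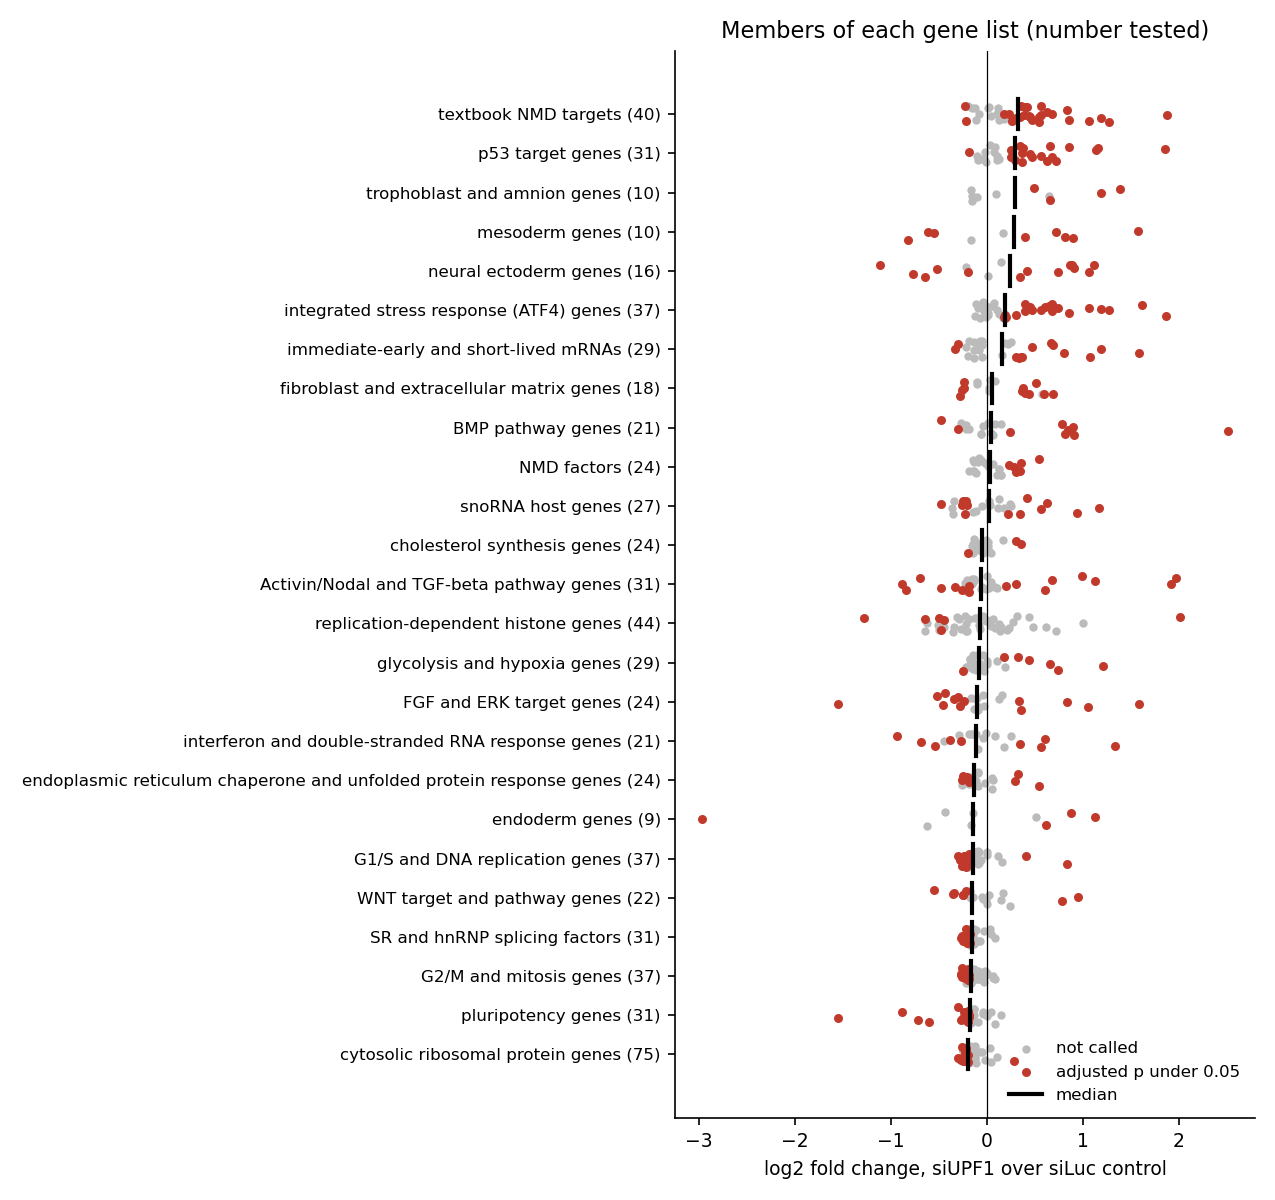
Log2 fold change (siUPF1 over siLuc control) of each tested member of 25 gene lists, with the number tested in brackets; red points passed an adjusted p of 0.05, grey points did not, and black bars are medians. List medians run from -0.20 for cytosolic ribosomal protein genes to 0.33 for textbook NMD targets.

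Among genes of ribosomes, splicing and cell division, a minority fell, by small amounts. Of 75 cytosolic ribosomal protein genes, 1 rose, 22 fell and 52 did not pass (1 and 32 adjusted over the list alone), with a median log2 fold change of -0.20. RPL19 stood at -0.30 (SE 0.08), RPS3A at -0.25 (SE 0.08) and RPL28, the riser, at 0.29 (SE 0.07), from 124 ± 3.13 to 151 ± 3.27 CPM (SD, n = 2 per group). Of 31 genes on a list of SR, hnRNP and other splicing factors, 10 fell and 21 did not pass (14 fell adjusted over the list alone). Their median was -0.16, with PTBP2 at -0.27 (SE 0.08), SNRNP70 at -0.25 (SE 0.07) and SRSF2 at -0.21 (SE 0.07). Of 37 G2/M and mitosis genes, 11 fell and 26 did not pass (14 fell adjusted over the list alone), with a median of -0.16, BUB1 at -0.26 (SE 0.07), HMMR at -0.27 (SE 0.07) and TOP2A at -0.26 (SE 0.07). Of 37 G1/S and DNA replication genes, 2 rose, 12 fell and 23 did not pass (2 and 13 adjusted over the list alone), with a median of -0.14, the kinase gene CDK6 at 0.84 (SE 0.07) and UHRF1 at -0.29 (SE 0.07). With the preset correlation camera called the ribosomal (Benjamini-Hochberg adjusted p = 1.62e-08), splicing (0.0002), G2/M (0.000228) and G1/S (0.00165) lists. Each call was lost with adjusted p = 0.671 with an estimated correlation.

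These small falls depended on single libraries and went in part with read density. With the trend on read density removed, ribosomal and splicing fallers numbered 1 and 1, the splicing median was -0.07, and G2/M and G1/S fallers numbered 8 and 8, while camera still called the ribosomal (adjusted p = 0.0104), splicing (0.0395), G2/M (0.0104) and G1/S (0.0205) lists. Without siUPF1 replicate 2 the ribosomal median was -0.11 and the splicing and G1/S medians were -0.09, and adjusted p was 0.0533 for the splicing list, 0.0514 for G2/M and 0.0533 for G1/S, and without control a it was 0.0505 for both cell cycle lists (camera). Over their alternatives adjusted p began at 1.83e-15 for the ribosomal, 1.26e-05 for the splicing, 1.69e-05 for the G2/M and 6e-04 for the G1/S list, and it ended at 0.671 for the first 3 and 0.775 for G1/S. Of ribosomal protein genes, 56 fell without siUPF1 replicate 1, 1 without control a, and 0 in edgeR without control b or without siUPF1 replicate 2 (26 and 3 at an unadjusted p under 0.05). Of the splicing genes, 18 fell without siUPF1 replicate 1, 3 without replicate 2, 2 without control b and 0 in edgeR without control a (1 unadjusted). Of the G2/M and G1/S genes, 0 fell in edgeR without control a (5 and 4 unadjusted), 4 and 4 without control b, and 2 and 6 without siUPF1 replicate 2. DESeq2 called 0 ribosomal and 0 splicing genes down (10 and 11 at an unadjusted p under 0.05), and of the G2/M and G1/S genes 2 and 5. Without control a the highest adjusted p of PTBP2 (0.1), SNRNP70 (0.346), SRSF2 (0.277), BUB1 (0.108), HMMR (0.123), TOP2A (0.23) and UHRF1 (0.0952) was reached, from lowest values of 0.00281, 0.00369, 0.00834, 0.000215, 8.05e-05, 0.000902 and 1.41e-05 (edgeR quasi-likelihood test). RPL28 reached 0.0789 without control b, from 0.000177. RPL19 and RPS3A reached 0.135 and 0.183 with the trend on read density removed, from 5.75e-05 and 0.00158, and did not pass under 4 and 5 of 11 alternatives. Several abundant transcripts sat near 1 read per transcript base, with GAPDH at 0.982, PTMA at 0.982, ACTB at 0.972 and RPL8 at 0.945, though LIN28A stood at 0.766 and EEF1A1 at 0.642, and the 99th percentile over all genes was 0.714. Genes at 0.75 reads per base or more had a median log2 fold change of -0.17 and a median ratio of -0.16 between siUPF1 replicates 2 and 1, while genes under 0.05 had 0.07 and 0.15. The ribosomal list had a median of -0.17 between siUPF1 replicates 2 and 1 and of -0.03 between controls b and a, with 67 of its 75 members over 0.5 reads per base. GAPDH, named after its value was seen, changed by -0.25 (SE 0.07), and by -0.06 once the trend on read density was removed, with an adjusted p of 0.388, the highest of alternatives that began at 3.56e-05 (edgeR quasi-likelihood test).

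**Figure D3:**
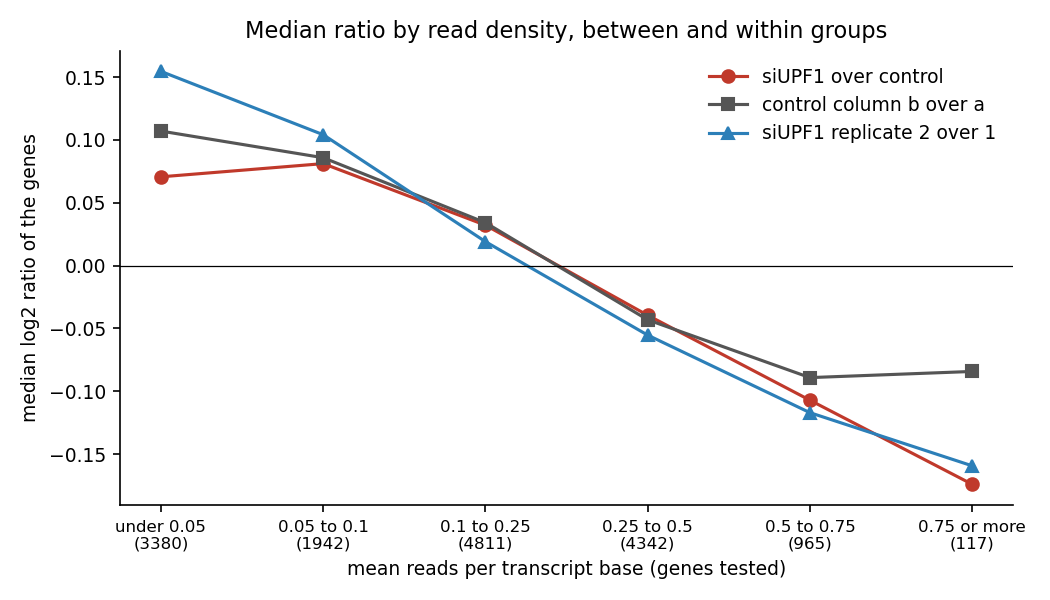
Median log2 ratio (vertical axis) of genes in 6 classes of mean reads per transcript base (horizontal axis, with genes tested) for siUPF1 over control (red circles), control b over a (grey squares) and siUPF1 replicate 2 over 1 (blue triangles). In every class the 3 medians have the same sign, from 0.07, 0.11 and 0.15 in the sparsest class to -0.17, -0.08 and -0.16 in the densest.

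Other groups changed in part. Of 29 immediate-early and short-lived mRNAs, 11 rose and 2 fell, the same counts adjusted over the list alone, with JUN at 1.08 (SE 0.08) beside FOSL1 and ATF3 given above. Of 29 glycolysis and hypoxia genes, 6 rose and 1 fell (5 and 1 adjusted over the list alone), with the hypoxia-inducible genes NDRG1 at 1.22 (SE 0.13), ADM at 0.75 (SE 0.08) and PFKFB4 at 0.66 (SE 0.09). Of 18 fibroblast and extracellular matrix genes, 7 rose and 4 fell (8 and 4 adjusted over the list alone), with FBN1 at 0.69 (SE 0.08), TNC at 0.59 (SE 0.08) and TAGLN at 0.44 (SE 0.08). Of 21 interferon and double-stranded RNA response genes, 4 rose and 5 fell, the same counts adjusted over the list alone, with IFIT3 at 1.33 (SE 0.24), MX1 at 0.61 (SE 0.14) and IRF9 at 0.56 (SE 0.14). Of 24 cholesterol synthesis genes, 2 rose and 1 fell (2 up adjusted over the list alone), with MVK at 0.36 (SE 0.08) and SQLE at -0.19 (SE 0.07). The adjusted p of MVK ranged from 2.52e-05 to 0.0835, highest without control b, and that of SQLE from 0.00306 to 0.442, highest without control a (edgeR quasi-likelihood test). Of 44 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 1 rose and 5 fell (1 and 3 adjusted over the list alone). HIST1H3G stood at -1.27 (SE 0.29) and HIST2H2BE at -0.50 (SE 0.17), while HIST1H1B rose by 2.01 (SE 0.49) from 0.419 ± 0.113 CPM (SD, n = 2) and stood at 1.31 without siUPF1 replicate 1, with an adjusted p of 0.141, the highest of alternatives that began at 5.44e-05 (edgeR quasi-likelihood test). HIST2H2BE reached an adjusted p of 0.285 without control b, from 0.00642, and HIST1H3G 0.0713 with DESeq2, from 8.78e-05. None of these 6 lists was called (camera, Benjamini-Hochberg adjusted p = 0.145, 0.628, 0.367, 0.509, 0.397 and 0.128 in this order), and no gene of the mitochondrial genome was in the table. The glycolysis list had a median of -0.08 and a mean of 0.05, and camera placed it down. Without siUPF1 replicate 1, 7 glycolysis and 8 cholesterol synthesis genes fell. Without control a, 7 immediate-early, 4 fibroblast and 3 interferon genes rose, and histone fallers numbered 2, against 1 without control b or without siUPF1 replicate 1. Interferon fallers numbered 1 without control a or without control b, and 0 in DESeq2 (2 at an unadjusted p under 0.05; edgeR called 5). Fibroblast fallers numbered 1 without control a or without siUPF1 replicate 1, and immediate-early fallers 0 in edgeR without control a (0 unadjusted; DESeq2 called 1). The histone list was called by camera with a filter of 5 CPM (adjusted p = 0.00559), without siUPF1 replicate 1 (0.00895) and with the trend on read density removed (0.0485), within a range that ended at 0.847. The cholesterol list was called without siUPF1 replicate 1 (camera, adjusted p = 0.00565), the lowest of a range that ended at 0.922.

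Transcript features that can trigger NMD were compared. An exon junction more than 50 nt downstream of the stop codon, in any annotated coding or NMD transcript of the gene, marked 4634 genes. A long 3' UTR marked 3360 genes and an upstream AUG 7618. Counts per gene cannot tell whether the transcript with the junction was expressed. Of genes with such a junction, 17.7% rose and 7.06% fell, against 16.2% and 11.3% of 8794 other coding genes, and their median log2 fold change was 0.01 against -0.03. Of genes with a long 3' UTR, 20.5% rose and 9.73% fell, against 15.5% and 9.87% of the others. Of genes with an upstream AUG, 17.7% rose, against 15.4% of the others. None of these 3 lists was called by camera with the preset correlation (Benjamini-Hochberg adjusted p = 0.403, 0.403 and 0.425), and 0 had an unadjusted p under 0.05. With an estimated correlation camera gave the junction list an adjusted p of 0.38. The test fry, which asks whether a set moves on balance, called the junction list at an adjusted p of 0.00617. Because fry does not set a list against other genes, it cannot tell whether junction genes differed from other coding genes.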

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

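The fits on genes under 0.25 reads per base and with the trend on reads per base removed were chosen after the data were seen; the others were planned. UPF1 fell past the threshold under all 11 alternatives that tested it, with log2 fold changes from -1.80 to -1.44. DESeq2 called 1274 genes up and 465 down, and a fold of at least 2 left 394 and 144. With single libraries left out the counts ran from 1444 to 2764 up and from 552 to 1522 down. Genes under 0.25 reads per base gave 1682 up and 1212 down, from 10133 genes tested, and 1682 and 918 were among the calls of the fit to all genes. Risers were 58.1% of these calls, and 64.8% of the calls over all genes, which is a different set. In the same genes the fit to all genes called more risers. It called 639, 487 and 1032 up and 332, 206 and 384 down at under 0.05, 0.05 to 0.1 and 0.1 to 0.25 reads per base. Trend removal gave 2382 up and 1641 down, of which 2138 and 1152 were among the calls of the uncorrected fit. Of 25 lists tested, camera called 8, and 0 with an estimated correlation (0 unadjusted) or with fry (8 at an unadjusted p under 0.05). It called 4 on genes under 0.25 reads per base, and between 5, without siUPF1 replicate 2, and 11, without siUPF1 replicate 1, with a library left out. On genes under 0.25 reads per base, where 5 G1/S members remained, their median was still -0.05 but camera placed the list up (adjusted p = 0.775). Of the transcript-feature lists, camera called 0 and fry, which was run on all libraries only, called 1. ATF4 went from -0.11 to 0.0394 with the trend removed. Of 98 other named genes, RLE, library size and limma-voom changed no call, DESeq2 ended 13, trend removal 9, and leaving out control a 19, control b 11, siUPF1 replicate 1 3 and replicate 2 7. Causes other than fewer genes or libraries were not tested. No paired analysis was possible because both control columns carry the same name and so no replicate number; the replicate block and the RPKM fits with their pseudocounts were not run. Depth limits the precision of genes near 1 CPM. GAPDH, PTMA, UBB and ACTB stood at 0.97 to 0.98 reads per base, and no gene with at least 100 counts exceeded 1.12. These values go with a ceiling near 1 read per base, under which the changes and the CPM of dense genes would be understated. The CPM of dense genes should therefore not be read as abundance, and how far their changes are understated was not tested. The SD of log2 fold change over genes was 0.074 at 0.75 reads per base or more and 0.66 under 0.05.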

Other observations

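The grouping of genes into families and the removal of the trend on read density were chosen after the data were seen, and the other tests below were set out before their results. Of 36 ADAM and ADAMTS proteases, which cut matrix and cell surface proteins, 16 rose and 6 fell, with a median log2 fold change of 0.18. Of 33 collagen genes, 11 rose and 6 fell (median 0.09), of 29 semaphorin and plexin genes, which guide axons, 11 rose and 6 fell (median 0.14), and of 19 integrin genes 6 rose and 1 fell (median 0.11). Of 509 ZNF zinc finger genes, 73 rose and 29 fell (median 0.04). Rows with only noncoding RefSeq transcripts held 291 risers and 58 fallers of 1616 (median 0.07). None of these families was called (camera, Benjamini-Hochberg adjusted p = 0.243, 0.335, 0.335, 0.364, 0.375 and 0.155 in this order). Few single genes passed among 51 proteasome subunits (2 rose, 49 did not pass; median -0.09), 40 respiratory complex I subunits (2 rose, 38 did not pass; -0.09) and 53 translation initiation factors (1 rose, 3 fell; -0.11). These lists each had a camera adjusted p of 0.0492. It became 0.912 for each with an estimated correlation (unadjusted p of 0.573, 0.54 and 0.556), and 0.618, 0.618 and 0.623 with the trend on read density removed.

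The small falls of ribosomal protein and pluripotency genes could come from counts that level off near 1 read per base, since the siUPF1 libraries were the deeper ones. Replicate 1 of siUPF1 was only 1.22% deeper than control b, yet its median ratios over that library were -0.0877 and -0.0992. These ratios cannot decide, because the density of the most densely covered genes differed between these libraries at nearly equal depth. GAPDH stood at 1.08 reads per base in control b and 0.963 in siUPF1 replicate 1, and PTMA at 1.06 and 0.953. Between libraries of one group, deeper over shallower, the ribosomal list had medians of -0.0344 (controls) and -0.1738 (siUPF1), and the pluripotency list -0.0834 and -0.0712, which met the condition set beforehand for this ceiling, so that it may account for part of the pluripotency fall. With the trend removed, the ribosomal median went from -0.20 to -0.0678, with 1 faller counted and camera adjusted p = 0.0104, and that median is within 2 SE (SE 0.04, from the medians within groups of 0.06 and -0.04), so for this list the read density and UPF1 loss cannot be told apart with 2 libraries per group. The pluripotency median went from -0.17 to -0.0846, with 6 fallers counted (camera adjusted p = 0.0196, against 0.671 in the uncorrected fit with an estimated correlation). Both lists stayed called, the outcome set beforehand as going against the density trend as the whole cause. The SE of 0.01 for the pluripotency median rests only on the medians within groups of 3e-04 and 0.0146. It is too uncertain to set this list apart from the ribosomal one, so the cause stays undecided here too. Of 6 members under 0.25 reads per base, where the medians of all genes were positive, 5 fell, which argues against the density trend for those members. A lower level of pluripotency transcripts after UPF1 loss stays open as a hypothesis, as does a difference in cell state between cultures, which was not tested.

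Genes carrying features that can trigger NMD were set against 10000 random sets matched on abundance and transcript length, since these properties may by themselves shift a median. The median of genes with an exon junction downstream of the stop codon, 0.0139, lay at percentile 100 of the matched sets, whose central range was -0.0382 to -0.0257, and that of genes with an upstream AUG, -0.0022, at percentile 100 of a range of -0.0228 to -0.0116. Length and abundance, matched in 8 bins per property, thus left these shifts in place in these libraries. The shifts are small, and camera did not call these lists. Random sets of genes hold no spread between libraries, so their ranges cannot tell whether such shifts exceed it. Between the controls, medians of read density classes ran from -0.0892 to 0.107. Genes with a long 3' UTR (0.0107) lay at percentile 0 of their matched sets (0.027 to 0.0442), an outcome that neither prediction covered. Transcript length includes the 3' UTR, so matching on it takes away part of the feature itself. This comparison therefore cannot tell whether a long 3' UTR goes with a rise or a fall.

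The rises of stress response and p53 target genes might rest on members that are also textbook NMD targets. Without the 9 shared genes the stress response list kept 28 members, of which 14 rose, with a median of 0.18 and a camera adjusted p of 7.84e-05. Without the 2 shared genes the p53 list kept 29, of which 16 rose and 1 fell, with a median of 0.26 and an adjusted p of 5.81e-05. Both p were adjusted over these reduced lists only. Membership shared with the NMD target list thus does not account for either rise. Members that the stress response and p53 lists share with each other, such as SESN2, were not removed. With all members both calls were lost with a camera adjusted p of 0.671 with an estimated correlation, under which no list was called. Stress from transfection is shared with the siLuc control, and whether the stress and p53 genes respond to UPF1 loss, to this siRNA or to its off-targets cannot be separated with siRNA against a single target and was not tested.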
